A study of Mus musculus with 4 samples.

How the data were processed

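The samples were 4 single-cell RNA libraries from mouse retina, 2 labelled Control and 2 labelled Diabetic. Live cells had been enriched for CD31 (PECAM1, a surface protein of endothelial cells) with beads before 10x Chromium 3′ library preparation. The deposited files held raw counts of unique molecular identifiers (UMIs), as the authors made them with Cell Ranger 7.0.0; the submitters' processing notes also named STAR 2.7.10b and the genome build mm10. The matrices held whole numbers for 55357 genes in called cells, and no normalization had been applied. The labels did not say whether the 2 libraries of a group came from separate animals, so the tests measured the spread between these libraries. The diabetes model, its duration and the number of retinas per library were not in the labels.

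Barcodes with at least 500 UMIs, at least 300 genes and at most 20% mitochondrial UMIs were kept. Doublets were called in each library with Scrublet in scanpy 1.11.5. Its automatic threshold marked under 0.5% of the barcodes of Diabetic 1, one of the larger libraries, so there by a rule fixed in advance the expected rate of 0.8% per 1000 cells was used. That rule covered only libraries above a set size, so the smaller Control 2 and Diabetic 2, also under 0.5%, kept the automatic threshold. As a result 6.37% of the passing barcodes of Diabetic 1 were removed, against 0.562%, 0.492% and 0.483% in Control 1, Control 2 and Diabetic 2. Cells of all libraries were clustered together from 2000 variable genes, 30 principal components, 20 neighbours and a Leiden resolution of 1, without batch correction (leidenalg 0.10.2, igraph 0.11.9). This gave 23 clusters, which were named from marker lists as endothelial, pericyte or smooth muscle, microglia or macrophage, neutrophil, rod, cone, bipolar and Müller glia classes. A cluster that also held markers of another class at 0.3 or more of that class's own level (0.5 for rods) was called mixed and left out of the classes. So was a cluster whose own markers lay under 0.3. Astrocyte, cone and epithelial markers did not count as those of another class, nor did rod markers in a cone cluster. The endothelial clusters were thus not screened for astrocyte markers by this rule. Those levels were set after the clusters had been seen. Endothelial cells were clustered again after each gene had been centred within its library, at a resolution of 0.8, which gave 10 subclusters. All class and subcluster names describe expression in these data and rest on no other assay.

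Counts were summed over the cells of a class in each library, and the libraries, not the cells, were the replicates. Differences were tested with edgeR 4.0.16 (TMM normalization, filterByExpr, quasi-likelihood F test, two-sided) in R 4.3.3, and adjusted p-values were from the Benjamini-Hochberg method. A gene was called at an adjusted p under 0.05. DESeq2 1.42.0 served as the second tool. Expression levels were the summed counts of a gene scaled to a common library total (CPM), without a pseudocount, and errors were the SD of 2 libraries or the SE of the fitted log2 fold change. Where both libraries of a group had no UMI, the fold was computed against a floor of 3 counts over the group. With 1 to 3 counts in a group, the ratio of sums was given with its 95% counting interval. Both cover counting error only. Classes and subclusters with at least 20 cells in every library were tested.

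Gene sets were 38 lists: tight and adherens junction, barrier transporters and transcytosis, sphingolipid metabolism, leukocyte adhesion and chemokines, NF-kB response, interferon response, MHC class I, MHC class II, angiogenesis, Norrin and Wnt, TGF-beta and BMP, shear stress, basement membrane, glycolysis, hypoxia, mitochondrial and nuclear genes of oxidative phosphorylation, oxidative stress, glucose and fatty acid response, cholesterol, endoplasmic reticulum stress, heat shock, immediate early genes, apoptosis and p53, complement and coagulation, cell cycle, ribosomal proteins, gliosis, microglial activation, microglial homeostasis, phototransduction, sex-linked genes, and transcripts of photoreceptors, Müller glia, pericytes, microglia, erythrocytes, and bipolar and amacrine cells. Each was tested against the other genes with camera (limma 3.58.1) at a preset correlation of 0.01 where at least 5 members were tested, and again with an estimated correlation. The fry test was a further alternative. The sphingolipid list was chosen because the study's paper is known to have examined that pathway on these libraries.

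The lists, tests, filters and rules for named genes were fixed before the data were examined. Among called genes of endothelial cells with a mean of at least 20 CPM and no overlap between groups, the 8 with the highest and the 8 with the lowest log2 fold change were named. A further 14 genes were named whatever their result. Up to 4 members of each list were named by the size of their change, some of which are not reported here, and in other classes and subclusters 4 genes per direction. Where no gene was called, 3 genes in each direction were given as values. With 2 libraries against 2, 33.3% of genes show no overlap between groups by chance. Other genes of the endothelial lists named in the text were chosen after their values were seen.

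An interaction of subtype and disease had been planned for arterial, capillary and venous endothelial subclusters. Of these, only the arterial-like subcluster had 20 cells in every library, so it was compared with the interferon-response-like subcluster, a choice made after seeing the data. Shares of cells were compared with an exact permutation test, which with 6 arrangements cannot give a two-sided p below 0.333. Their 95% intervals were Clopper-Pearson intervals. For shares of cells with a UMI of a gene, cells were also thinned to 1000 UMIs, and cells with fewer were left out.

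The edgeR procedure was tested on simulated counts in which every gene had the common dispersion observed for its cells. No difference in spread between genes was simulated, and the subclusters of the interaction were drawn without a shared library effect. The values below hold for that simpler setting. In endothelial cells it recovered 98.5% of genes changed 4-fold, 57.7% of those changed 2-fold and 26.7% of those changed 1.5-fold, with 5 false calls of 127. In pericytes, which had fewer cells, it recovered 80.5%, 18.6% and 1.82%, and in the interaction 83.3% at 4-fold and 31.8% at 2-fold. The alternatives covered normalization, the filter on low counts, the tool, the replicate number as a term, each library left out, mitochondrial and doublet limits, cluster resolution, thinned cells and equal subclusters. Cluster resolution was varied for the share of endothelial cells only. The setting of equal subclusters held no cells of subcluster 9, which had no Control cell. With a library left out, the lone library of its group was assumed to vary like the pair of the other group. Gene positions came from GENCODE release M21 on GRCm38, the assembly named mm10 by the submitters. Of the 55357 gene identifiers, 52081 were in that release, 49847 of them with the same symbol. Genes with close copies in the genome, among them Serpina3n, Ifi27l2a, Hspa1b, the haemoglobin genes and the ribosomal protein genes, have less certain counts, since reads shared between copies could not be traced in the files. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 were used.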

Results

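The study's title asks about the endothelial cells of the blood-retina barrier in diabetic retinopathy, and the libraries compare retinal cells of Control and Diabetic mice. Control 1 held 6394 barcodes and 54901304 UMIs, Control 2 3091 and 29792902, Diabetic 1 7991 and 58792636, and Diabetic 2 3934 and 41239892. After filtering, 5835, 2426, 7388 and 3502 cells were kept in that order. Their median UMIs were 3752, 4418, 3309 and 5131 per cell, and their median mitochondrial shares 4.33%, 4.45%, 2.45% and 3.24%. The endothelial class held 790, 309, 1599 and 757 cells with 2911604, 1561041, 5985637 and 4162425 UMIs. Besides endothelial cells, the enriched samples held rods, Müller glia, cones, pericytes, bipolar cells and microglia. A cluster named neutrophil from its markers held 26, 12, 91 and 34 cells, in which S100a8 and S100a9 together had 4151 and 0 CPM in Control and 82544 and 69438 CPM in Diabetic, so its Control 2 cells had none of these markers.

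The first comparison asked which genes differed between Diabetic and Control endothelial cells. Several genes known from inflamed and venous endothelium were higher in both Diabetic libraries. Lcn2, an iron-siderophore binding protein of acute inflammation, went from 2.77 ± 2.46 CPM in Control to 655 ± 213 CPM in Diabetic (SD, n = 2 each). Lrg1, a secreted glycoprotein that alters TGF-beta signalling in vessels, went from 3.72 ± 4.77 to 386 ± 84.3 CPM. Ackr1, the chemokine receptor that marks venules, went from 3.20 ± 1.79 to 201 ± 44.6 CPM, and Vcam1, which binds leukocytes, from 55.3 ± 26.7 to 325 ± 72.1 CPM. Serpina3n, an acute-phase protease inhibitor, had no UMI in Control and 84.5 and 99.9 CPM in Diabetic, at least 135-fold higher against 3 counts over the group. The chaperone gene Hsph1 was lower, at 79.1 ± 9.37 CPM in Control and 10.5 ± 0.0685 CPM in Diabetic.

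In edgeR, 326 of 12318 genes were higher and 147 lower in Diabetic endothelial cells. The log2 fold changes were 8.15 ± 0.39 (SE) for Lcn2 (edgeR adjusted p = 1.05e-05), 7.12 ± 0.44 for Lrg1 (2.61e-05) and 5.80 ± 0.28 for Ackr1 (1.05e-05). The adjusted p of Serpina3n was 1.23e-05. Among called genes with a mean of at least 20 CPM, the other large increases were in Cd14, a receptor for lipopolysaccharide (5.55 ± 0.74, 0.00317), Ptgs2, which makes prostaglandins (4.77 ± 0.40, 0.000216), Ch25h, which makes 25-hydroxycholesterol (4.34 ± 0.30, 4.77e-05), and Atp8b1, a phospholipid flippase (3.31 ± 0.20, 2.61e-05). At that level, the largest decreases after Hsph1 (-2.90 ± 0.16, 2.39e-05) were in Ifi27l2a, an interferon-induced gene (-2.54 ± 0.18, 5.54e-05), and Gkn3 (-1.79 ± 0.42, 0.0467), followed by the endothelial repressor Bcl6b (-1.56, 0.00114). Fbln2 (-1.46, 0.00618) and Ecm2 (-1.34, 0.00441), both matrix proteins, also fell, as did Car4, a carbonic anhydrase of capillaries (-1.28, 0.000487), and the chaperone partner Dnaja1 (-1.28 ± 0.14, 0.000951). Without Control 1, Lcn2 was at 7.16 and Lrg1 at 5.75, and without Control 2, Gkn3 was at -0.83. Cd14 was at 4.84 without Diabetic 2.

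The positions are on GRCm38, where these are protein-coding genes, and the 3′ counts do not separate exons. Lcn2 (ENSMUSG00000026822) spans positions 32384633 to 32388252 of chromosome 2, and Lrg1 (ENSMUSG00000037095) 56119678 to 56122001 of chromosome 17. Ackr1 (ENSMUSG00000037872) spans 173331886 to 173333750 of chromosome 1, Serpina3n (ENSMUSG00000021091) 104406729 to 104414329 of chromosome 12, and Hsph1 (ENSMUSG00000029657) 149614287 to 149636376 of chromosome 5.

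**Figure D1:**
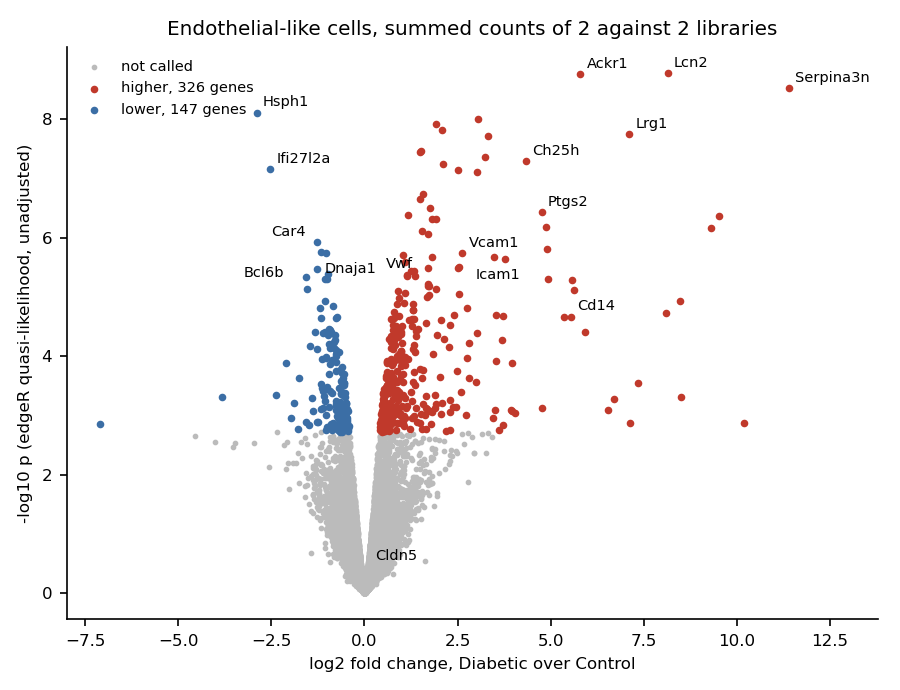
Each point is one of the 12318 genes tested in endothelial cells, with the log2 fold change of Diabetic over Control on the x axis and minus log10 of the unadjusted edgeR p on the y axis. The 326 genes called higher (red) and 147 called lower (blue) are coloured, Lcn2 lies at a log2 fold change of 8.15, and x positions of genes without a Control UMI, such as Serpina3n, are fitted values and no bounds.

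Cells of a few subclusters carried most of these UMIs. Subcluster 9, a venous-like group, held 0 of 790 and 0 of 309 Control endothelial cells, which allows shares of up to 0.380% and 0.971%, and 72 and 52 cells in the Diabetic libraries. Subcluster 7, which got no name and had 2 neutrophil genes, S100a9 and S100a8, among its leading genes, held 19 and 2 Control cells and 206 and 103 Diabetic cells. Its first genes, Gsto1 and Psca, came from the 19 cells of Control 1, which held 5507 of the 5531 Gsto1 UMIs and 2461 of the 2466 Psca UMIs of that library's endothelial cells. Diabetic endothelial cells had 71 Gsto1, 3 Psca, 443 S100a8 and 589 S100a9 UMIs. Together, subclusters 7 and 9 held 90.7% of the Lcn2 UMIs of Diabetic endothelial cells (85.3% in subcluster 9), 90.0% of those of Lrg1, 88.6% of Ackr1, 76.6% of Vcam1 and 75.3% of Icam1, but 18.7% of Hsph1. Because Lcn2, Lrg1, Ackr1 and Vcam1 are themselves venous markers in the naming list, the size of these subclusters is not a separate result. Without subclusters 7 and 9, an alternative chosen after seeing the data, 58 genes were higher and 53 lower. Of these, 55 and 50 were among the 326 and 147. Cd14, Ptgs2, Vcam1, Vwf and Gkn3 were then no longer called. Gkn3, Ifi27l2a, Fbln2 and Vegfc, all lower, were among the leading genes of the arterial-like subcluster. That subcluster held 133 of 790 and 65 of 309 Control and 210 of 1599 and 110 of 757 Diabetic endothelial cells. With equal numbers of cells from each subcluster, Gkn3 was not called but Fbln2 was. Ifi27l2a was called in all 15 alternatives that tested it, but not in the interferon-response-like subcluster alone (-0.96, edgeR adjusted p = 0.624).

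Counts per cell gave the same direction. In Control 1 and Control 2, 0.380% and 1.62% of endothelial cells had an Lcn2 UMI, against 10.9% and 13.6% in Diabetic 1 and Diabetic 2. In rods, which should lack Lcn2, the shares were 2.80% and 6.29% in Control and 7.70% and 9.55% in Diabetic. The Control endothelial shares lay below those of rods and are not read as expression, and rods do not measure the background of endothelial cells. After thinning to 1000 UMIs, the Lcn2 shares were 0.152% and 0.380% in Control and 6.39% and 9.13% in Diabetic endothelial cells, and 0.450%, 0.750%, 1.76% and 0.947% in rods. Lrg1 UMIs were in 0.127% and 0.971% of Control and 16.4% and 20.1% of Diabetic endothelial cells (thinned 0%, 0%, 10.7% and 13.1%). In rods they were in 0%, 0%, 2.18% and 2.63% (thinned 0%, 0%, 0.586% and 0.430%). Hsph1 UMIs were in 20% and 27.5% of Control and 3.82% and 5.02% of Diabetic endothelial cells (thinned 7.47%, 7.98%, 1.16% and 0.761%), and in 14.9%, 19.7%, 8.74% and 11.9% of rods (thinned 3.74%, 2.25%, 1.72% and 1.38%). Median UMIs were 2744, 3533, 2738 and 3948 in endothelial cells and 2366, 3974, 2487 and 4175 in rods. Thinning left out 134, 46, 221 and 100 endothelial cells and 384, 133, 495 and 94 rods.

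**Figure D2:**
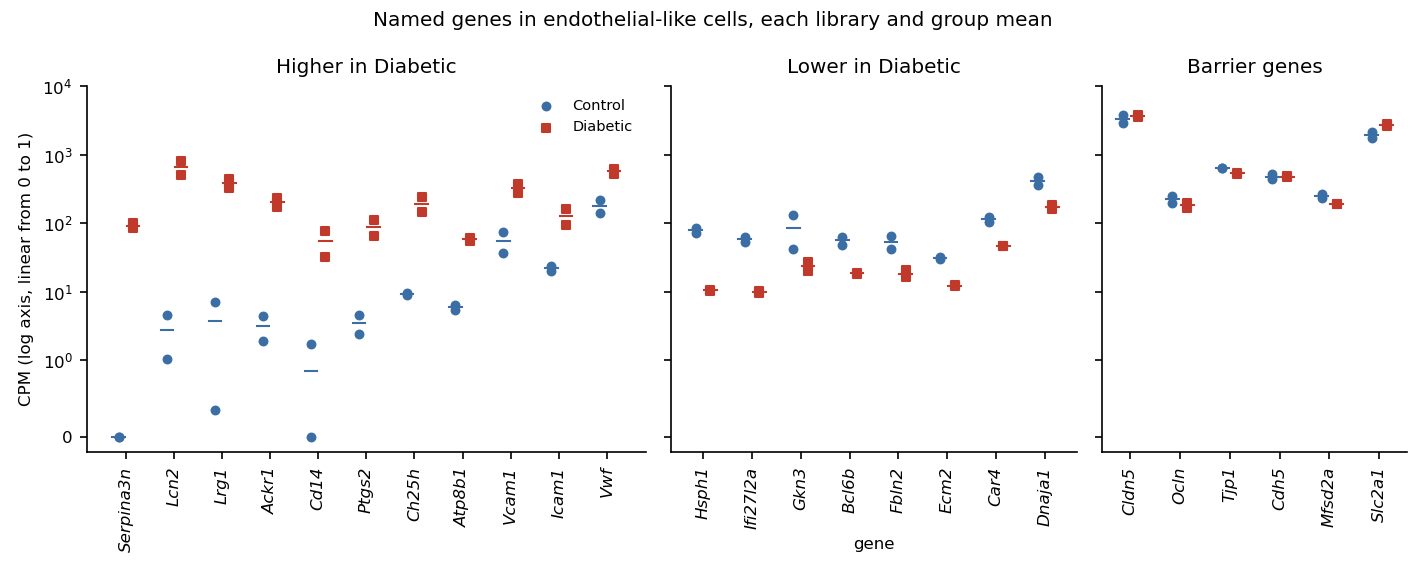
CPM of named genes in the endothelial cells of each library, on a log axis that is linear from 0 to 1, with one point per library (Control circles, Diabetic squares) and a short line at the mean of each group of 2. Lcn2, Lrg1, Ackr1 and Vcam1 are higher in both Diabetic libraries and Hsph1 is lower, with 79.1 CPM in Control and 10.5 CPM in Diabetic.

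Of 14 tested genes of the leukocyte adhesion and chemokine list, 8 were higher and 1 lower (adjusted over the list alone, 9 higher and 1 lower), with a median log2 fold change of 2.59 (camera adjusted p = 6.4e-41, but adjusted p = 0.243 with an estimated correlation). Besides Lcn2, Lrg1, Ackr1 and Vcam1, these were Icam1 (2.55 ± 0.27, edgeR adjusted p = 0.000949), which binds leukocyte integrins, Csf1 (0.80, 0.0291) and the selectins Sele and Selp, which slow leukocytes on the vessel wall. Sele and Selp had no UMI in Control, and Sele stood at 23.2 and 27.4 CPM in Diabetic. The chemokine scavenger Ackr3 fell (-0.94, 0.0457). In the NF-kB list, 7 of 19 genes were higher and 0 lower (adjusted over the list alone, 13 and 1; median 0.65, camera adjusted p = 3.8e-15, adjusted p = 0.346 with an estimated correlation). They included Cebpd (1.93, edgeR adjusted p = 0.000241), Socs3 (1.72, 0.000364) and Bcl3 (1.38, 0.00441), all induced by cytokines. Equal numbers of cells from each subcluster left out subcluster 9, which had no Control cell. That subcluster held 65.8% of the Vcam1, 56.8% of the Icam1 and 51.9% of the Vwf UMIs of Diabetic endothelial cells. Lower values for these genes were thus built into the setting. With equal numbers, the adhesion list had a median of 0.57 over its tested members. The NF-kB list had one of 0.09 and was not called by camera. Icam1 was at 0.75 and, like Vcam1 and Vwf, not called. Without subclusters 7 and 9, the medians of these lists were 1.01 and 0.28.

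In the complement and coagulation list, 6 of 14 genes were higher and 0 lower (adjusted over the list alone, 9 and 0; median 1.04, camera adjusted p = 1.01e-11, adjusted p = 0.302 with an estimated correlation). Vwf, the platelet-binding protein stored in endothelial cells, went from 177 to 572 CPM (1.71, edgeR adjusted p = 0.000951). Cd59a, which limits complement on the cell surface, also rose (0.80, edgeR adjusted p = 0.00292). With equal numbers of cells from each subcluster, the list's median was 0.39 and Vwf was not called. MHC class II had 2 of 6 genes higher and 0 lower (adjusted over the list alone, 2 and 0; median 1.09, camera adjusted p = 0.000629, adjusted p = 0.491 with an estimated correlation). MHC class I had 0 of 19 called (median 0.17, camera adjusted p = 0.20). Of 34 interferon response genes, Ifitm2 (0.92, edgeR adjusted p = 0.00317), Ifitm3 (0.80, 0.00319) and Iigp1 (0.81, 0.0195) rose and Rsad2 fell (-0.77, 0.0119), with a median of -0.12 (adjusted over the list alone, 3 higher and 2 lower; camera adjusted p = 0.430). These list calls changed with single libraries. Without Control 1, the MHC class II list was at 0.52 and not called, MHC class I at -0.08, and the interferon list was called lower at -0.33. Without Control 2, MHC class I was called higher at 0.43 and MHC class II was at 1.86. The interferon list was called lower at -0.21 without Diabetic 2 but higher at 0.11 with equal numbers of cells from each subcluster.

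Junction genes, which seal the blood-retina barrier, gave no called change with all 4 libraries. None of the 18 tight and adherens junction genes was called by edgeR, over all genes or adjusted over the list alone, with 2 at an unadjusted p under 0.05 and 0 called by DESeq2. Their median was 0.02, their mean -0.04 and the direction of the camera test down (adjusted p = 0.430). Without Control 1, however, camera called the list lower at a median of -0.12. Cldn5, the main claudin of the barrier, was at 3342 CPM in Control and 3645 CPM in Diabetic (0.13 ± 0.13, edgeR adjusted p = 0.659). The values were -0.28 for Ocln (0.304), -0.24 for Tjp1 (0.222) and 0.00 for Cdh5 (0.997). Among 23 barrier transporters, 2 were higher and 0 lower (adjusted over the list alone, 4 and 5), the amino acid transporter Slc38a5 (1.33, 0.00606) and the lactate transporter Slc16a1 (0.54, 0.0206). That list had a median of -0.14, a mean of 0.03 and a camera test direction of down (adjusted p = 0.517). It was called lower at -0.27 without Control 1. The lipid transporter Mfsd2a, which restrains transcytosis, had 249 and 192 CPM (-0.37, edgeR adjusted p = 0.106), and the glucose transporter Slc2a1 was at 0.46 (0.0628). Plvap, a protein of fenestrae, had 3 and 7 UMIs in the Control libraries, 41 in Diabetic 1 and 1 in Diabetic 2 (0.77, 0.745), and Angpt2 was at 0.25 (0.671).

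Of 41 sphingolipid genes, 3 were higher and 1 lower (adjusted over the list alone, 3 and 2; median 0.13, camera adjusted p = 0.0768). This list was examined by the study on these libraries, so its counts are not independent evidence. Acer2, an alkaline ceramidase, went from 180 to 352 CPM (0.98, edgeR adjusted p = 0.00441), Ugcg, which makes glucosylceramide, rose by 1.32 (0.00229) and the lipid phosphatase Plpp1 by 0.66 (0.0436). The sphingosine-phosphate phosphatase Sgpp2 fell by 0.64 on the log2 scale (0.0313). Without Control 2, camera called the list higher at a median of 0.17.

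Of 24 genes of glucose, insulin and fatty acid response, 8 were higher and 0 lower (adjusted over the list alone, 9 and 1; median 0.16, camera adjusted p = 1.25e-06, adjusted p = 0.243 with an estimated correlation). Angptl4, which inhibits lipoprotein lipase, rose by 1.93 (edgeR adjusted p = 0.00154), Igfbp3 by 1.37 (0.00111) and Ucp2 by 1.26 (0.00101). Txnip, which is induced by glucose, rose from 279 to 424 CPM (0.61, 0.0303). Cholesterol genes had 0 of 19 higher and 2 lower (adjusted over the list alone, 0 and 6; median -0.39, camera adjusted p = 0.000185, adjusted p = 0.302 with an estimated correlation), among them the sterol sensor partner Insig1 (-0.96, edgeR adjusted p = 0.0127). Of 24 oxidative stress genes, 3 were higher (adjusted over the list alone, 15 higher and 0 lower; median 0.39, camera adjusted p = 2.81e-06, adjusted p = 0.243 with an estimated correlation), the peroxide-removing enzymes Gpx1 (0.69, edgeR adjusted p = 0.00931) and Prdx6 (0.44, 0.0474) and the superoxide dismutase Sod2 (0.47, 0.0459). Mitochondrial genes of oxidative phosphorylation had 3 of 12 lower (adjusted over the list alone, 4; median -0.43, camera adjusted p = 0.000369, adjusted p = 0.491 with an estimated correlation). The nuclear genes had 1 of 69 higher, Ndufa6 at 0.49 (edgeR adjusted p = 0.0331), and none adjusted over the list alone (median 0.12, camera adjusted p = 0.00701, adjusted p = 0.491 with an estimated correlation). Median mitochondrial shares of endothelial cells were 6.31% and 5.58% in Control and 3.01% and 3.83% in Diabetic. The shares were also lower in both Diabetic libraries in every other class. In Control against Diabetic, they were 3.20% and 2.85% against 1.82% and 2.19% in rods. In pericytes they were 8.13% and 7.83% against 4.01% and 4.90%. Barcodes over the mitochondrial limit were 511 of 6394 and 638 of 3091 in Control and 90 of 7991 and 405 of 3934 in Diabetic. The lower shares were thus not particular to endothelial cells, and their cause was not tested. Glycolysis had 0 of 19 called (median 0.09, camera adjusted p = 0.164), and the list was called higher at 0.18 without Control 1. The cholesterol list was not called with equal numbers of cells from each subcluster (-0.19) or without subclusters 7 and 9 (-0.15). Without Control 2, its median was -0.20 and that of the mitochondrial genes -0.28. The median of the glucose, insulin and fatty acid list was 0.43 without Control 1, 0.09 without Diabetic 1 and 0.27 without Diabetic 2. Hypoxia had 2 of 19 lower (adjusted over the list alone, 1 higher and 3 lower), the collagen hydroxylases P4ha1 (-0.93, edgeR adjusted p = 0.00967) and P4ha2 (-0.84, 0.0408). Its median was 0.04, its mean -0.10 and its camera direction down (adjusted p = 0.601).

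Of 13 heat shock genes, 6 were lower and 0 higher (adjusted over the list alone, 8 and 0; median -0.51, camera adjusted p = 6.88e-15, adjusted p = 0.243 with an estimated correlation). They included Hsp90aa1 (-0.96, edgeR adjusted p = 0.00426) and Chordc1 (-0.77, 0.00678). Of 20 immediate early genes, 14 were higher and 0 lower (adjusted over the list alone, 19 and 0; median 0.66, camera adjusted p = 5.59e-26, adjusted p = 0.243 with an estimated correlation), among them Fos (1.5, edgeR adjusted p = 4e-05), Atf3 (1.58, 0.000127) and Nr4a1 (1.28, 0.00319). Of 78 ribosomal protein genes, 17 were higher and 0 lower (adjusted over the list alone, 61 and 0; median 0.35, camera adjusted p = 4.49e-16, adjusted p = 0.491 with an estimated correlation), such as Rpl10 (0.65, edgeR adjusted p = 0.0134). Endoplasmic reticulum stress had 2 of 23 higher (adjusted over the list alone, 3 higher and 1 lower; median 0.05, camera adjusted p = 0.0875), Atf3 and Xbp1 (1.10, edgeR adjusted p = 0.000819). Apoptosis and p53 had 2 of 20 higher (adjusted over the list alone, 3 higher and 1 lower; median 0.05, camera adjusted p = 0.340), Pmaip1 (0.74, edgeR adjusted p = 0.00532) and Gadd45b (0.70, 0.019). Cell cycle had 2 of 14 higher (also 2 adjusted over the list alone; median 0.25, camera adjusted p = 0.140), Ccnd1 (0.73, edgeR adjusted p = 0.00989) and Hmgb2. With equal numbers of cells from each subcluster, the median was 0.33 for immediate early and 0.16 for ribosomal protein genes.

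Among vessel signalling lists, 3 of 28 angiogenesis genes were lower and 1 higher (adjusted over the list alone, 10 lower and 3 higher; median -0.16, camera adjusted p = 0.0141, adjusted p = 0.567 with an estimated correlation). Vegfc, a lymphatic and vascular growth factor, fell by 1.17 (edgeR adjusted p = 0.0163), and Mcam, an adhesion molecule, rose by 1.05 (0.0211). Norrin and Wnt had 1 of 24 lower (also 1 adjusted over the list alone; median -0.14, camera adjusted p = 0.180), the receptor Fzd6 (-0.47, edgeR adjusted p = 0.0404). TGF-beta and BMP had 2 of 23 higher and 1 lower (adjusted over the list alone, 4 and 2; median 0.09, camera adjusted p = 0.104). These were the matricellular proteins Ccn1 (2.08, edgeR adjusted p = 2.61e-05) and Ccn2 (1.09, 0.00821) and the TGF-beta binding protein Ltbp4 (-1.06, 0.00215). Shear stress had 1 of 17 higher (also 1 adjusted over the list alone; median 0.09, camera adjusted p = 0.340), Ddah1 (0.60, edgeR adjusted p = 0.0426). Basement membrane had 2 of 28 higher and 1 lower (the same counts adjusted over the list alone), with Nid1 at 0.70 (edgeR adjusted p = 0.0126) and Timp3 at -0.58 (0.0313). Its median was -0.01, its mean 0.16 and its camera direction up (adjusted p = 0.684). The angiogenesis list was not called without Control 2 (-0.11) or Diabetic 1 (-0.19), with equal numbers of cells from each subcluster (-0.10) or without subclusters 7 and 9 (-0.09). Norrin and Wnt was called lower without Control 1 (-0.22) or Diabetic 2 (-0.16), and TGF-beta and BMP (0.26) and shear stress (0.17) were called higher without Control 2.

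Markers of other cells were tested in the same way. Photoreceptor transcripts, which come from other cells, had 0 of 19 called (adjusted over the list alone, 2 lower; median -0.57, camera adjusted p = 2.81e-06, adjusted p = 0.567 with an estimated correlation). They made up 1.56% and 1.01% of endothelial UMIs in Control and 1.06% and 0.705% in Diabetic. Phototransduction had 2 of 21 lower (adjusted over the list alone, 17; median -0.63, camera adjusted p = 1.67e-09, adjusted p = 0.491 with an estimated correlation). Pericyte transcripts had 1 of 14 higher (adjusted over the list alone, 4; median 0.29, camera adjusted p = 0.0166, adjusted p = 0.491 with an estimated correlation) and microglia transcripts 1 of 9 (adjusted over the list alone, 3; median 0.44, camera adjusted p = 0.0435, adjusted p = 0.657 with an estimated correlation). Müller glia transcripts had 1 of 13 higher, Cp, a copper oxidase (0.59, edgeR adjusted p = 0.0204; also 1 adjusted over the list alone; median 0.14, camera adjusted p = 0.340). Bipolar and amacrine transcripts had 0 of 10 called (median 0.07, camera adjusted p = 0.859). Gliosis had 7 of 22 higher and 1 lower (adjusted over the list alone, 11 and 2; median 0.39, camera adjusted p = 6.07e-15, adjusted p = 0.253 with an estimated correlation), with Lcn2, Serpina3n, Cebpd and Socs3 among them. Microglial activation had 4 of 10 higher (adjusted over the list alone, 4 higher and 1 lower; median 0.94, camera adjusted p = 1.25e-06, adjusted p = 0.243 with an estimated correlation), among them the MHC class II genes Cd74 and H2-Ab1. Erythrocyte transcripts (4 tested), microglial homeostasis (3) and sex-linked genes (4) had 0 called over all genes and too few members for camera. The neutrophil genes S100a8 and S100a9 together had 8.59 and 0 CPM in Control and 154 and 26.9 CPM in Diabetic endothelial cells. Pericyte and microglia transcripts were not called without Control 1 (0.08 and 0.04), microglia transcripts not without Diabetic 1 (0.23), and microglial activation not without Control 2 (0.48) and at 0.34 without Diabetic 1. With equal numbers of cells from each subcluster, microglial activation (0.22) and pericyte transcripts (-0.08) were not called, and gliosis was at 0.13. Without Control 2, the medians were 0.66 for gliosis, 1.30 for microglia, 0.48 for pericyte and -0.87 for photoreceptor transcripts. Photoreceptor transcripts and phototransduction were at -0.21 and -0.25 without Control 1 and at -0.30 and -0.36 without Diabetic 2, and photoreceptor transcripts at -0.87 without Diabetic 1. Without the low-UMI cluster, neither was called (-0.12 and -0.13), nor were photoreceptor transcripts with no doublets removed (-0.22).

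**Figure D3:**
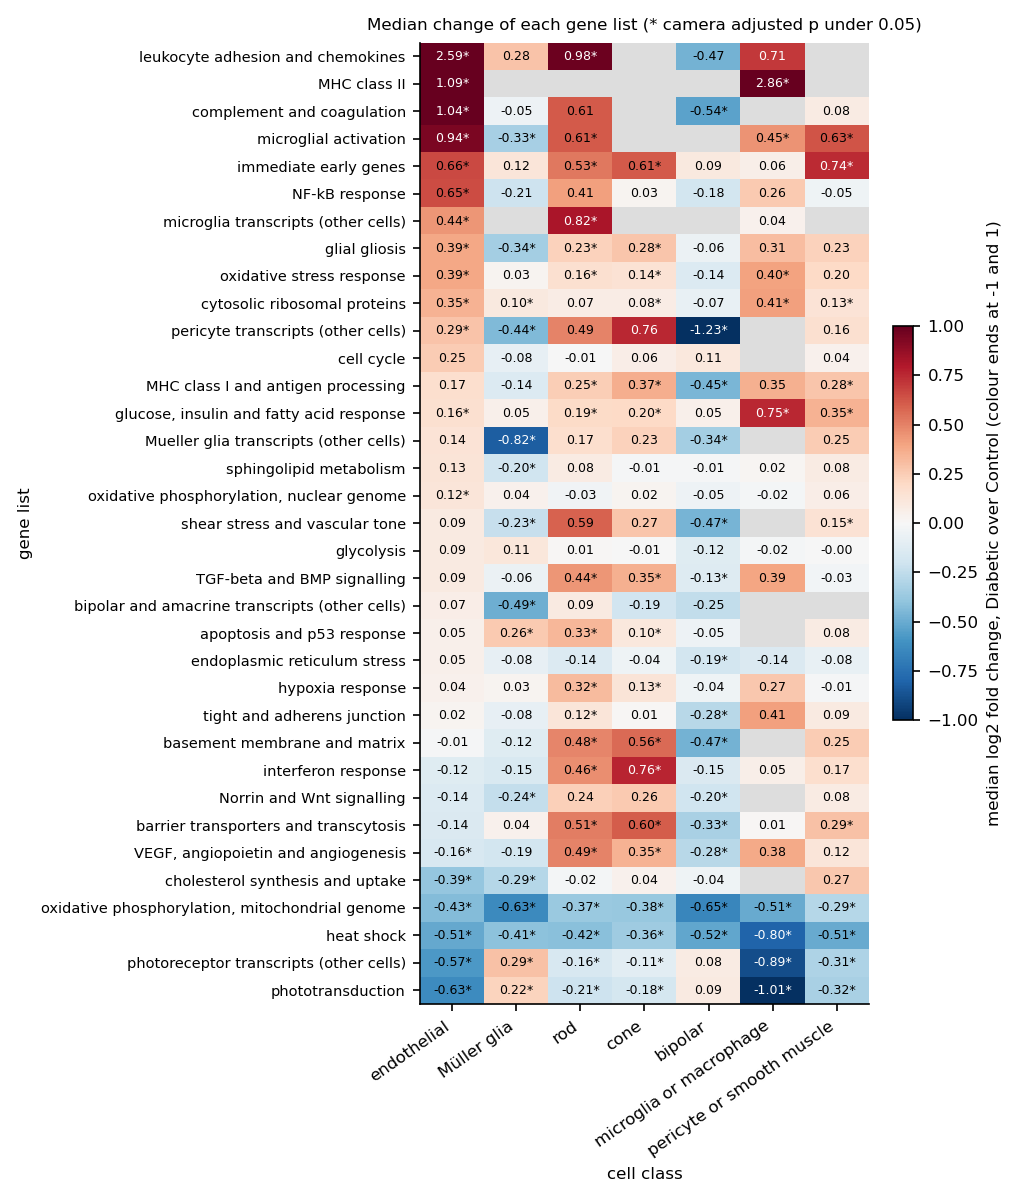
Median log2 fold change of Diabetic over Control for gene lists in each cell class, as a heat map with the values printed, the colour ending at -1 and 1, grey where fewer than 5 members were tested, and a star at a camera adjusted p under 0.05 with the preset correlation. In endothelial cells the leukocyte adhesion list stands at 2.59 and the heat shock list at -0.51.

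Of 35 lists tested in endothelial cells, camera placed 13 up and 6 down with the preset correlation and 0 with an estimated correlation, and fry called 3 up and 1 down. The gene counts depended on the libraries and settings used. They were 509 higher and 416 lower without Control 1, 919 and 791 without Control 2, 233 and 161 without Diabetic 1 and 167 and 135 without Diabetic 2, and 86 and 30 when no doublets were removed. With 263 cells per library thinned to 1000 UMIs, 56 genes were higher and 19 lower, and with equal subclusters 23 and 19. Atp8b1 and Ecm2 were not called with equal subclusters, nor Bcl6b, Fbln2 and Car4 after thinning. Gkn3 was called in 10 of 15 alternatives, Acer2 in 12 of 16 and Txnip in 9 of 16. Among the endothelial genes named, Txnip, Sgpp2, Plpp1, Fzd6, Ddah1, Nid1, P4ha2, Ndufa6, Prdx6, Sod2 and Hmgb2 were called neither without Diabetic 1 nor without Diabetic 2. Rsad2 and Insig1 were not called without Diabetic 1, nor Slc16a1, Iigp1, Mcam, Timp3, Gpx1, Chordc1, Gadd45b, Ccnd1, Rpl10 and Cp without Diabetic 2.

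Endothelial cells made up a larger share of the kept cells in Diabetic libraries. They were 13.5% (95% interval 12.7 to 14.4) and 12.7% (11.4 to 14.1) in Control and 21.6% (20.7 to 22.6) and 21.6% (20.3 to 23.02) in Diabetic. The means were 13.1% ± 0.567 and 21.6% ± 0.0191 (SD, n = 2), a difference of 8.49 points that exceeded the spread between libraries, with an exact permutation two-sided p of 0.333, the smallest that 6 arrangements allow. Bead enrichment acts on this share. Rods were 44.6% and 43.9% of cells in Control and 39.05% and 35.9% in Diabetic. Müller glia were 9.73% and 16.5% in Control and 9.19% and 12.4% in Diabetic, so the groups overlapped. Mixed clusters with endothelial markers (5, 10 and 12), kept out by a level set after seeing the data, held 9.25% and 10.5% of Control and 12.1% and 13.6% of Diabetic cells. Within the endothelial class, cluster 4, with low UMI totals, held 63.2% and 62.1% of Control and 43.0% and 40.4% of Diabetic cells. Cluster 22 held 0 and 0 Control cells and 112 and 69 Diabetic cells.

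The next comparison asked whether the change was seen in each endothelial subcluster. In the arterial-like subcluster (133, 65, 210 and 110 cells), 53 genes were higher and 76 lower by edgeR. Fabp4, a fatty acid carrier, fell by 4.30 on the log2 scale, Hba-a1 by 3.48, Hbb-bs by 3.06 and Hsph1 by 2.60, while Zc3h6 (2.47), Gpr160 (1.54), Cebpd (1.29) and Galk1 (1.29) rose. The haemoglobin genes belong to the list of erythrocyte transcripts. Their changes are not read as endothelial expression, here or in the other subclusters, and the source of this RNA was not tested. Without Control 1, Hbb-bs was at -1.79, and Fabp4 (-2.67) and Hba-a1 (-2.15) were not called. Gpr160 was not called without Control 1 or Diabetic 1, and Galk1 was called in none of the fits that left out 1 library. In the interferon-response-like subcluster (145, 55, 200 and 94 cells), 4 genes were higher and 12 lower. There S100a6 (2.14), Fos (0.78), Slc16a1 (0.71) and Igfbp7 (0.60) rose and Hsph1 (-2.86), Dnaja1 (-1.34), Hsp90aa1 (-0.96) and mt-Rnr2 (-0.96) fell. In subcluster 0, 25 genes were higher and 34 lower, with Prdx5 (1.91), Plpp1 (1.88), Cd9 (1.62) and Crip1 (1.60) up and Hsph1 (-2.62), Bcl6b (-1.92), Stip1 (-1.59) and Heatr5a (-1.48) down. In subcluster 5, led by immediate early and heat shock genes, 9 were higher and 10 lower, with Socs3 (1.94), Pim3 (1.41), Ccn1 (1.28) and Nr4a1 (1.22) up and Ifi203 (-1.37), mt-Rnr2 (-1.04), mt-Rnr1 (-1.02) and Dnaja1 (-0.98) down. Without Control 1, Hsph1 was at -1.52 in subcluster 0 and Ifi203 at -0.46 in subcluster 5, neither called. Without Diabetic 1, Socs3 was the only one of the genes named in subcluster 5 that was called.

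Subcluster 3, led by pericyte and photoreceptor genes, had 67 genes higher and 12 lower. Serpina3n was at least 16.9-fold higher there, Lcn2 rose by 6.33, Hbb-bs by 5.90 (1.39 and not called without Diabetic 1), and the ratio for Ackr1 was 61.7 (16.8 to 513). Hsph1 (-2.25), Flrt2 (-2.10), Proser2 (-1.40) and Lrit1 (-1.30) fell. Without Control 1, Lcn2 was at 4.6 there, and Flrt2, Proser2 and Lrit1 (-0.69) were not called, nor were these 3 without Diabetic 1 or Diabetic 2. Subcluster 2, with low UMI totals, had 0 genes called by edgeR, with 170 of 2430 at an unadjusted p under 0.05 and 0 called by DESeq2. Its values were 1.02 for Mgp, 1.74 for Junb, 1.33 for Cd59a, -0.97 for Hspa8, -1.48 for Dnaja1 and -0.99 for Ptn. DESeq2 called 1 higher and 1 lower in subcluster 0, 23 and 4 in subcluster 3, and 10 and 11 in the arterial-like subcluster. The totals of called genes without Control 1, Control 2, Diabetic 1 and Diabetic 2 in turn were 0, 41, 32 and 29 in subcluster 0, 0, 0, 33 and 40 in the interferon-response-like subcluster, 13, 3, 2 and 8 in subcluster 2, 35, 282, 43 and 64 in subcluster 3, 60, 60, 2 and 21 in subcluster 5, and 143, 103, 43 and 57 in the arterial-like subcluster.

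The difference between the arterial-like and interferon-response-like changes was then tested by itself. Of 8736 genes, 5 differed in edgeR, and 508 were at an unadjusted p under 0.05. The haemoglobin genes Hbb-bs and Hba-a1 and the genes S100a6, a calcium-binding protein, Cdh13, an adiponectin-binding cadherin, and Mal, a membrane raft protein, passed the test. As erythrocyte transcripts, the haemoglobin genes are not read as endothelial changes. S100a6 was at -0.62 in the arterial-like and 2.14 in the interferon-response-like subcluster, Cdh13 at -1.46 and 1.06, and Mal at 0.43 and -0.38. The difference, interferon-response-like minus arterial-like, lost its call for Hba-a1 without Control 1 (3.22, against 5.04), for Cdh13 without Control 2 (1.70, against 2.42) and for Mal without Diabetic 2 (-0.62, against -0.79). Without Control 1, Hbb-bs was at 2.36 (against 3.65), S100a6 at 3.75 (2.73) and Cdh13 at 3.93. Without Control 1, Control 2 or Diabetic 1, 29, 19 and 11 genes passed.

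Müller glia, the main support cells of the retina, had lower levels of their own marker genes in the Diabetic libraries. All 13 Müller glia genes of the list were lower (13 also adjusted over the list alone; median -0.82, camera adjusted p = 2.17e-30, adjusted p = 0.592 with an estimated correlation), among them the potassium channel Kcnj10 (-1.23), the water channel Aqp4 (-0.87) and the retinoid-binding protein Rlbp1 (-0.86). In all, 349 genes were higher and 583 lower of 13336 in edgeR, and 121 and 251 in DESeq2. The opioid precursor Penk (3.44, edgeR adjusted p = 0.00648), the glutathione peroxidase Gpx3 (2.46), Crhbp (1.87) and Chrnb1 (1.85) rose, and Ccn2 (-1.80, 0.00125), the thyroid hormone deiodinase Dio2 (-1.59), mt-Rnr1 (-1.42) and Omg (-1.42) fell. The gliosis list had 1 of 21 higher and 9 lower (adjusted over the list alone, 5 and 11; median -0.34, camera adjusted p = 0.001, adjusted p = 0.832 with an estimated correlation). Cholesterol genes had 5 of 19 lower (also 5 adjusted over the list alone; median -0.29, camera adjusted p = 2.91e-05, adjusted p = 0.592 with an estimated correlation). Photoreceptor transcripts, which come from other cells, had 3 of 19 higher (adjusted over the list alone, 7; median 0.29, camera adjusted p = 3.5e-06, adjusted p = 0.832 with an estimated correlation). They made up 5.14% and 4.93% of Müller glia UMIs in Control and 6.42% and 6.04% in Diabetic. Most cells of the class, 1527, were in cluster 8, with a median of 1518 UMIs and rod markers at 0.443 of the rod level. More RNA of other cells was thus not told apart from lower expression of the marker genes. Without Control 1, 1607 genes were called, with Penk at 6.56 and Crhbp at 3.52, and without Diabetic 2, Penk was at 2.15 and Gpx3 at 1.19.

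Rods and cones, which came from the same libraries, shared 142 genes called higher and 92 called lower. If calls were independent, which is not so for classes of the same libraries, 13.5 and 7.64 would be shared. Selenbp1, a selenium-binding protein, rose in rods from 2.58 to 50.9 CPM (4.30, edgeR adjusted p = 5.22e-08) and in cones by 4.96 (2.71e-08). In rods 1124 of 14901 genes were higher and 858 lower in edgeR (444 and 456 in DESeq2). Igfbp7 (1.52), Mgp (1.52) and Ly6a (1.41), which are abundant in vascular cells, were among the highest of the called genes with a mean of at least 20 CPM. Lars2 (-1.30), Cdcp3 (-1.26), mt-Rnr1 (-1.24) and mt-Rnr2 (-1.20) fell. Of 21 phototransduction genes, 8 were lower in rods and 0 higher (adjusted over the list alone, 14 lower and 1 higher; median -0.21, camera adjusted p = 2.23e-06, adjusted p = 0.536 with an estimated correlation). Of 13 heat shock genes, 10 were lower (adjusted over the list alone, 11 lower and 1 higher; median -0.42, camera adjusted p = 3.35e-11, adjusted p = 0.536 with an estimated correlation), and of 17 immediate early genes 9 were higher and 1 lower (adjusted over the list alone, 13 and 1; median 0.53, camera adjusted p = 3.79e-08, adjusted p = 0.536 with an estimated correlation). In cones 163 of 12035 genes were higher and 109 lower (20 and 45 in DESeq2), with Col4a3, a basement membrane collagen (1.81), Ly6c1 (1.78) and Chrnb1 (1.73) up and Cdcp3 (-1.46), mt-Rnr1 (-1.39), mt-Rnr2 (-1.30) and Lars2 (-1.01) down. The mitochondrial ribosomal RNAs mt-Rnr1 and mt-Rnr2 made up 4.02% and 3.44% of endothelial UMIs in Control and 1.47% and 2.05% in Diabetic. Rod counts were 732 without Diabetic 1 and 1065 without Diabetic 2. Without Diabetic 1, Mgp was at 0.89 in rods, and Lars2 (-0.94) was not called. Without Control 2, Lars2 was at -0.51 in rods, and at -0.37 and not called in cones. Cone counts were 542 without Control 1, 179 without Control 2 and 118 without Diabetic 1.

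Microglia or macrophages had higher levels of some MHC class II genes, which present antigen, and lower Mrc1, a marker of perivascular macrophages. Of 5 MHC class II genes, 3 were higher (also 3 adjusted over the list alone; median 2.86, camera adjusted p = 1.57e-09, adjusted p = 0.581 with an estimated correlation), among them H2-Aa (3.83) and H2-Eb1 (3.60). The ratio for H2-Ea was 45.7 (12.5 to 381) and for Tcim 43.2 (7.53 to 1728). The chemokine Ccl7 (-5.60), Fcrls (-4.11), the mannose receptor Mrc1 (-2.76) and Dab2 (-2.10) fell. Without Diabetic 1, H2-Aa (2.35) and H2-Ea were not called and H2-Eb1 was at 2.7, and without Diabetic 2, Tcim and Dab2 (-1.73) were not called. H2-Eb1 was at 2.55 without Control 1, and Ccl7 at -4.80 without Control 2. In all 9 genes of 3019 were higher and 9 lower in edgeR (7 and 6 in DESeq2), from 56, 28, 66 and 41 cells, and 50 were called without Control 1 and 92 without Control 2. Bipolar cells had 3 genes higher and 3 lower of 11142 in edgeR (0 and 3 in DESeq2). S100a9 was at least 14.1-fold higher there, Tmsb15b1 rose by 2.82 and Selenbp1 by 2.15, and Id1 (-1.73), mt-Rnr1 (-1.72) and Plac9a (-1.28) fell. The neutrophil genes S100a8 and S100a9 together stood at 28.0 and 19.1 CPM in Diabetic bipolar cells and at 34.6 and 19.0 CPM in Diabetic rods. Free neutrophil RNA was thus not told apart from expression in bipolar cells. Without each library in turn, 228, 96, 25 and 29 bipolar genes were called, and S100a9 and Tmsb15b1 were not called without Diabetic 1, nor Selenbp1 without Diabetic 2.

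Pericytes or smooth muscle cells had 0 of 5432 genes called in edgeR, with 254 at an unadjusted p under 0.05, and 0 in DESeq2. Their values were 2.56 for Angptl4, 1.70 for Fosb, -1.42 for Kcnv2, -0.97 for mt-Rnr1 and -1.35 for Igfbp5, and the ratio for Fabp4 was 15 (3.92 to 128). Without each library in turn, 21, 38, 1 and 2 genes were called.

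**Figure D4:**
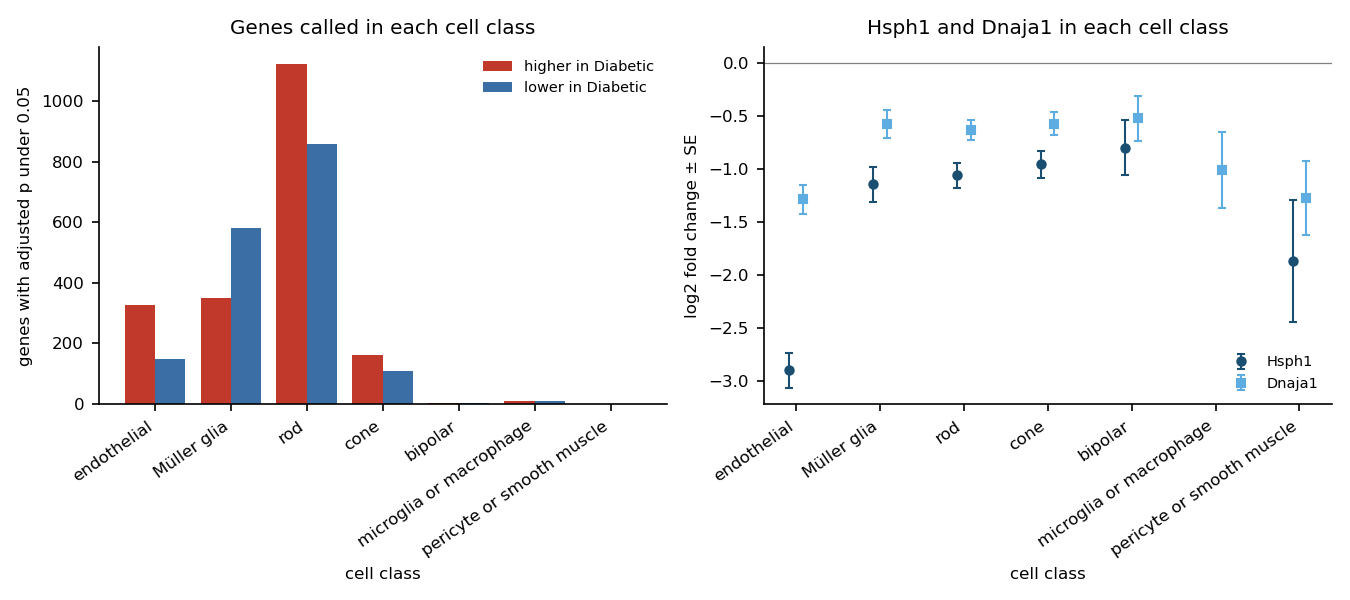
Left, the number of genes called higher and lower by edgeR in each cell class, as bars from 0, with 1124 and 858 in rods, 326 and 147 in endothelial cells and 0 in pericytes. Right, the log2 fold change of Hsph1 and Dnaja1 in each class with its SE, all below 0, with Hsph1 at -2.90 in endothelial cells and -1.06 in rods, and no Hsph1 value in microglia.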

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

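The tests of RNA from other cell classes, of neutrophils, of microglia and of handling that reached every cell class were chosen after the results were seen, as were the choice of the interferon-response-like subcluster and the fits of the mixed clusters.

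In the adhesion list, 8 of 14 genes were higher in Diabetic endothelial cells and 1 was lower, and 4 explanations were tested. RNA from the other named cell classes is argued against for part of the list. Of the 8 members called higher, 5 (Vcam1, Sele, Selp, Ackr1 and Csf1) had a Diabetic endothelial CPM at least 2 times that of every other class tested and of the neutrophil cluster. Mixed clusters, among them cluster 18 with astrocyte markers, were not compared, so RNA from such cells was not tested. RNA from neutrophils as the source of Lcn2 and Lrg1 is argued against too, because the share needed was at least 96.6 times the share that S100a8 and S100a9 allowed, with 18.0% needed and 0.186% allowed for Lcn2 in Diabetic 1, although neutrophil RNA was not wholly absent. RNA from microglia or macrophages as the source of Icam1 needed at least 657 times the share that the C1q genes allowed. More venous cells among the endothelial cells of the Diabetic libraries stay open. The median log2 fold change of Nr2f2 (0.44 ± 0.20), Slc38a5 (1.33) and Ephb4 (0.05) was 0.44. A median under 0.5 had been set beforehand to count against more venous cells. The value met that bound, but by less than its SE, and Slc38a5 alone lay well above it. More venous cells and an effect of diabetes in the same cells cannot be told apart.

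Of 13 heat shock genes 6 were lower, and of 78 ribosomal protein genes 17 were higher, in Diabetic endothelial cells. Neither list was called with an estimated correlation (camera adjusted p = 0.243 and 0.491), and the ribosomal median was 0.35, or 0.16 with equal numbers of cells from each subcluster. The tests that follow did not use the ribosomal protein genes. For the heat shock genes, barcodes of high mitochondrial share in the Control libraries are argued against, as the list's median was -0.54 with barcodes up to 10% mitochondrial UMIs, against -0.51 with all. A difference in handling or collection that reached every cell class remains a candidate explanation for them, since the heat shock median was under -0.3 in 6 of the 6 other classes, although diabetes could reach every class as well. The arms of the clock differed by over 0.3 in 2 classes, endothelial cells (0.93) and Müller glia (-0.33), in opposite directions. That was few enough to meet the bound set beforehand to count against retinas collected at another time of day in the 2 groups. Rods (0.27) and cones (0.28) lay just under 0.3, so this explanation is left open. The allowance for values just under 0.3 was not part of the bound set beforehand. No label gives the time or order of collection, so time of day and diabetes cannot be told apart here.

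Of 20 immediate early genes, 14 were higher in Diabetic endothelial cells, although the list was not called with an estimated correlation (camera adjusted p = 0.243). A dissociation response that differed between the groups and reached every cell class stays open, since the immediate early median was over 0.3 in 3 of the 6 other classes. A different mix of endothelial subclusters also stays open, because the median fell from 0.66 to 0.33 with equal numbers of cells of each subcluster, between the bounds of 0.2 and 0.5. Subcluster 5 was itself led by immediate early genes, so equal numbers also level the expression tested, and this setting cannot decide. An effect of diabetes was not tested apart from these explanations.

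The difference between the change in the interferon-response-like and the arterial-like subcluster passed its own test for 5 genes, among them the haemoglobin genes, which are erythrocyte transcripts. On the log2 scale, interferon-response-like minus arterial-like, it was 3.65 for Hbb-bs (edgeR adjusted p = 0.000262), 5.04 for Hba-a1 (0.00142), 2.73 for S100a6 (0.00495), -0.79 for Mal (0.0315) and 2.42 for Cdh13 (0.0407). Each was measured in 2 libraries per group, and the call was lost for Hba-a1 without Control 1, for Cdh13 without Control 2 and for Mal without Diabetic 2.

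Clusters that held endothelial markers with those of other cells, and so belonged to no class, also differed between the groups. In cluster 5, Egr1 was 1.87 higher on the log2 scale (edgeR adjusted p = 0.00227), and 18 genes were higher and 9 lower. In cluster 10, Lrg1 was 6.44 higher (8.93e-07), and 146 genes were higher and 73 lower. In cluster 12, the erythrocyte transcript Hba-a2 was 4.30 higher, with a ratio of 20.6 (counting interval 6.90 to 101) over 3 Control counts, and 66 genes were higher and 49 lower.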

How the results depend on the processing

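The alternatives without subclusters 7 and 9, without the low-UMI cluster, with the mixed clusters, with expected-rate doublets in every library, and arterial against capillary were chosen after seeing the data. Of 2325 values for endothelial genes, 1840 were the same, 257 lost the call, 167 gained it, 59 moved and 2 reversed. Values that were the same stayed on their side of the threshold. Between uncalled fits they could still change sign by up to 1 SE, and a larger change of sign counted as moved. Values without an adjusted p were the same within 1 SE and moved beyond it. Reversed values changed sign with a call in at least 1 of the 2 fits. Of 719 values for genes of other cells, 568 were the same, 113 lost the call and 38 gained it. Of 551 list values, 470 stayed on their side of the camera threshold, 58 lost the call and 18 gained it. In 5 a direction that was called in at least 1 of the 2 fits turned. The median changed sign in 38 of the 551, over 14 lists, and the camera direction in 34, over 12 lists. All 326 higher and 147 lower genes kept their direction with RLE factors, no filter and DESeq2, and 190 of 193 and 112 of 113 of those tested did so after thinning. Lcn2, Lrg1, Ch25h, Hsph1 and Dnaja1 stayed called in all 16 alternatives, with Lcn2 from 3.02 to 9.27, Lrg1 from 2.56 to 10.02 (the upper ends, without Control 2, rest on 3 and 1 Control counts) and Hsph1 from -3.04 to -2.67. Hbb-bs, at 0.66 and not called, was at -1.41 without Diabetic replicate 1 and up to 1.48 without another library. S100a6, at -2.03 and not called, was at 0.67 without Control replicate 1 and at -2.87 without Control replicate 2. The median of pericyte transcripts, 0.29, was -0.15 with the mixed clusters, -0.0602 when thinned and -0.0788 with equal subclusters. That of interferon genes, -0.12, was 0.11 with equal subclusters, and that of Müller glia transcripts, 0.14, was -0.15 with the mixed clusters. The cause was not tested, for these or for the changes of counts given next. The alternative of endothelial cells chosen by single marker genes left 3, 3, 7 and 14 cells and gave no value.

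The counts of genes higher and lower in endothelial cells, 326 and 147, were 809 and 479 with no low-count filter, 207 and 91 with DESeq2, 207 and 90 with mitochondrial shares up to 10%, 86 and 30 with no doublets removed, 56 and 19 when thinned (with 5156 genes tested), 23 and 19 with equal subclusters and 58 and 53 without subclusters 7 and 9. With expected-rate doublets removed in every library, they were 269 and 163. Leaving out one library gave 167 to 919 higher and 135 to 791 lower. Of 35 lists, 19 were called by camera, 0 with an estimated correlation, 4 by fry, and 17 to 21 without one library. The difference in endothelial share, 8.49 points, was 9.57 with mitochondrial shares up to 10%, 7.52 at a Leiden resolution of 0.5, and 8.09 to 8.89 without one library. At the resolution of 0.5, a cluster of 215 cells led by Lcn2, Lrg1, Serpina3n and Ackr1 was called mixed and left the endothelial class. Its astrocyte and endothelial markers stood at 0.678 and 0.679 of the levels of those classes. Genes were not tested at that resolution. The 5 genes of the subtype difference became 19 with no filter, 10 with no doublets removed, 11 with subtypes from uncentred values, 12 for arterial against capillary with no doublets removed, and 5 to 29 without one library. Of the 5, 1 lost its call without each of Control 1 (Hba-a1), Control 2 (Cdh13) and Diabetic 2 (Mal).

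With no filter, the changed genes were 1477 in Müller glia, 577 in cones, 94 in bipolar cells, 41 in microglia, 6 in pericytes, 97 in subcluster 1, 7 in subcluster 2, 141 in subcluster 3 and 61 in subcluster 5. With DESeq2 they were 372 in Müller glia, 900 in rods, 65 in cones, 3 in bipolar cells, 2 in subcluster 0, 27 in subcluster 3 and 21 in subcluster 6. With RLE factors subcluster 2 had 5. The labels do not say whether the 2 libraries that carry one replicate number share more than that number. Their gene-wise deviations correlated at 0.178 in endothelial cells, -0.0108 in Müller glia and 0.272 in rods. With that replicate block, 817 genes were higher and 600 lower in endothelial cells, and the changed genes were 4582 in rods, 1095 in cones, 64 in bipolar cells, 99 in microglia, 6 in pericytes, 153 in subcluster 1, 27 in subcluster 2 and 91 in subcluster 5. Without one library, they ranged from 636 to 1607 in Müller glia, 732 to 2085 in rods, 118 to 542 in cones, 25 to 228 in bipolar cells, 12 to 92 in microglia and 1 to 38 in pericytes. In subclusters 0, 1, 2, 3, 5 and 6 the ranges were 0 to 41, 0 to 40, 2 to 13, 35 to 282, 2 to 60 and 43 to 143. In simulated pericyte counts, with the common dispersion for every gene, edgeR recovered 80.5% of 4-fold, 18.6% of 2-fold and 1.82% of 1.5-fold changes.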

Other observations

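Some genes were called in the same direction in several cell classes. Of the genes tested in the 7 classes, 91 were higher in at least 3 and 26 lower in at least 3, and none of these was called in the opposite direction in another class. In all, 16 genes were higher in at least 4 classes, and only some of them are named here. The linker histone gene H1f2 was higher in 5 classes, and Selenbp1, Tmsb15b1, Gadd45b, a stress-induced gene, Cirbp, a cold-induced RNA-binding protein, and Lrg1 in 4. The neutrophil genes S100a8 and S100a9 were also higher in 4. The mitochondrial ribosomal RNA mt-Rnr1 was lower in 5 classes, and mt-Rnr2, mt-Nd2, Hsp90ab1, Ahsa2, Dnaja1 and Hsph1 in 4. Endothelial cells and rods shared 94 higher and 36 lower genes, against 19.2 and 8.33 if calls were independent. Müller glia and rods shared 194 higher genes, against 27.9, but 35 lower genes against 34.8. The classes came from the same libraries and carry each other's free RNA, so these counts are not independent of one another.

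In rods, the p53 targets Cdkn1a, which halts the cell cycle, and Bbc3, which promotes apoptosis, were 2.86 and 2.32 higher on the log2 scale (edgeR adjusted p = 0.000411 and 0.00133), and Gadd45b was 2.43 higher (1.18e-05). In Müller glia, S1pr1, a sphingosine-phosphate receptor, was at -1.14 (0.00134). These genes were chosen after their values were seen, and the other members of their lists are not given here for these cells.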
